A study of Mus musculus with 2 samples.

How the data were processed

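Non-parenchymal liver cells of 2 male mice aged 8 to 10 weeks, 1 wild type and 1 homozygous mutant littermate, were pulled down with magnetic beads against F4/80, a surface protein of mouse macrophages. Each suspension was loaded for a target capture of 10000 cells with droplet reagents that tag the 3' end of each transcript with a cell barcode and a unique molecular identifier (UMI), per the labels. The deposited matrix holds whole-number UMI counts per gene and cell for both libraries together, made by the authors with Cell Ranger 3.0.1, per the file headers and the submitters' processing notes. The genome build was GRCm38.p5 and R 3.6.1 was also used, per the submitters' processing notes. The annotation release, and whether reads were subsampled to equal depth when the libraries were joined, are not given in the sources used here.

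Each barcode ends in the number 1 or 2, which splits the cells into 2 libraries. Nothing in the labels used here ties either number to a mouse, so no genotype was attached to a library, neither from its values nor from the order of the samples. All values are given for library 1 and library 2, ratios are library 2 over library 1, and whether a difference goes with the genotype was not analysed here. There was 1 mouse per genotype and cells are not replicates, so no test between libraries was run and no difference has a replicate check. Shares carry exact Clopper-Pearson 95% intervals, CPM (UMIs of a gene scaled to a common class total) exact Poisson 95% intervals, and ratios conditional exact 95% intervals. These cover counting error only.

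Cells with at least 200 genes and at most 20% mitochondrial UMIs were kept. Scrublet, run per library in scanpy 1.11.5, marked 3 cells (0.0860%) of library 1 and 4 cells (0.0576%) of library 2. A caller that marks under 0.5% of cells was taken as not having worked, so no doublets were left out and droplets with several cells remain among the kept cells. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen within each library and merged. Both libraries were clustered together with 30 principal components, 15 neighbours and the Leiden algorithm (leidenalg 0.10.2) at resolution 1. No integration across libraries was used. Other tools were python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, umap-learn 0.5.12 for the neighbour graph and matplotlib 3.10.9.

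Clusters were named from 23 marker lists, of which 1 marks proliferation. Lists of close relatives were joined (dendritic subtypes other than plasmacytoid, both monocyte lists, both endothelial lists, T with natural killer, B with plasma), which left 16 classes. The score of a class was the mean of its higher-scoring markers, each scaled from its lowest to its highest log2 CPM over the clusters. The joining and the score were chosen after the clusters had been seen, while the lists were fixed before the data were examined. A name needed at least 3 markers, each present in at least 10% of the cells and past the middle of its range. Leading genes were the top 10 by fold, taken once against the clusters that scored for other classes and once against all other cells. A cluster stayed unnamed if another class held more of the first 10, or if its median depth was less than that of its library divided by 3 and either set held no marker of its own class. Clusters 3 and 5 scored as Kupffer-like and had such markers in the first set alone, so they stayed unnamed. Classes are called Kupffer-like and so on, since they rest on markers alone.

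UMIs were summed per class and library and scaled by the class total over all genes to give CPM. Classes with at least 50 cells in each library were compared. A count of 0 was set to a floor of 3 UMIs in that library, and such a gene is said to be at its bound. For 18 gene lists, the median log2 ratio was taken over members with at least 10 CPM in either library. Its percentile among 10000 random lists of equal size, matched on mean expression, describes these libraries and is no p-value. The lists were heme and iron handling, NRF2 targets, MHC class II, inflammatory cytokines and NF-kB targets, interferon response, alternative activation and anti-inflammatory, scavenger and complement, lysosome, cholesterol and lipid, lipid-associated macrophage, dissociation and stress, proliferation, extracellular matrix turnover, globin and erythroid RNA, hepatocyte RNA, platelet RNA, mitochondrial RNA and ribosomal proteins. Cd163 stood in 2 of them.

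The genes named were set by a rule. Among genes with at least 50 CPM and at least 30 UMIs in either library, these were the 12 highest and 12 lowest ratios whose interval excludes 0 in Kupffer-like cells, and the 5 and 5 in each other class, without numbered predicted genes. Members of the fixed lists that met the same minimum could also be named, and Hmox1, Slc40a1, Spic, Cd163, Marco, Clec4f, Timd4, H2-Aa, Il1b, Tnf and Il10 were always given for Kupffer-like cells. Results for 2 further genes of the fixed lists, and a test that needed 1 of them, are not reported here. Gene positions come from GENCODE release M21 (GRCm38), matched by Ensembl gene identifier. It held 26042 of the 26078 identifiers in the matrix, and all 192 named or listed genes were found under the same symbol.

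The filters, comparisons, gene lists, naming rule and most alternatives were fixed before the data were examined. The alternatives set at that stage were a minimum of 500 genes, at most 10% mitochondrial UMIs, doublets kept, resolutions 0.5 and 2, 3000 variable genes, a median-of-ratios size factor, CPM without globin, hepatocyte, mitochondrial and ribosomal protein genes, Kupffer-like cells chosen by markers in each cell, thinning to 1000 UMIs per cell, and list members with at least 50 CPM. Those chosen after seeing the data left out shallow barcodes whose sequence occurs in both libraries, allowed 40% mitochondrial UMIs, left out the 6% of cells with the highest scrublet scores, compared the largest Kupffer-like clusters alone, or named shallow clusters from the first set of leading genes alone.

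The ratios and list percentiles were tested on simulated data, with 200 of 3433 genes changed by known folds. Both simulated libraries were drawn from the profile of library 1 summed over all kept cells, at the UMI total of each library. The interval held the true ratio for 95.0% of unchanged genes, and for 98%, 92%, 90% and 92% of genes changed 0.25-, 0.5-, 2- and 4-fold. It excluded 0 on the right side for 100% of changed genes at each size. A list with changed genes reached percentile 100, and 5 of 100 lists of unchanged genes fell outside the middle 95%. The counts were drawn with counting error alone, which the intervals assume, so good coverage was built in. The simulation says nothing on spread between cells or mice, and its sums were larger than those of the classes compared.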

Results

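Single-cell RNA was measured in F4/80-enriched liver cells of 2 mice, 1 wild type and 1 homozygous mutant littermate. The mutant mice have fragile red cells and hemolytic anemia. The study asked how the uptake of red cells by liver macrophages shapes their expression program. The 2 libraries are known here by number only, so each comparison is between library 1 and library 2 and not between genotypes. Library 1 held 8907 barcodes with 33099802 UMIs, between 500 and 37085 per barcode (median 2647). Library 2 held 9726 barcodes with 56947765 UMIs, between 592 and 80846 per barcode (median 4017). The matrix listed 26078 genes, of which 7588 had no UMI.

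Mitochondrial transcripts made up a median of 24.3% of UMIs in library 1 and 14.2% in library 2. More than 20% mitochondrial UMIs were found in 5384 barcodes (60.4%) of library 1 and 2783 barcodes (28.6%) of library 2. After filtering, 3488 cells (39.2%) of library 1 and 6942 cells (71.4%) of library 2 remained, with 14117134 and 45802199 UMIs. The kept cells had a median of 2848 UMIs in library 1 and 4597 in library 2. Of the kept cells, 815 in library 1 (23.4%) and 44 in library 2 (0.634%) carried a barcode sequence that also occurred in the other library with over 5 times as many UMIs. Shares are therefore also given without these shallow barcodes.

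**Figure D1:**
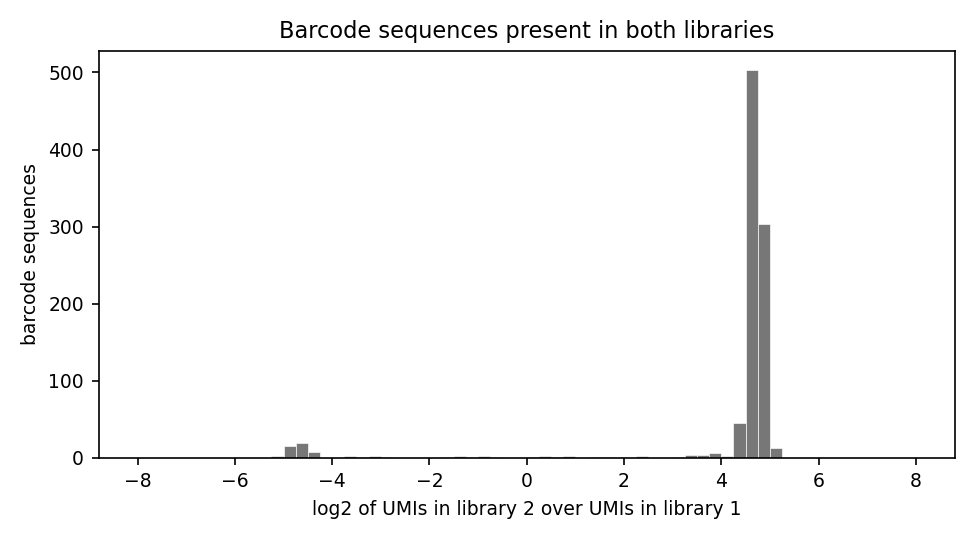
Number of barcode sequences present in both libraries by the log2 ratio of their UMIs (library 2 over library 1), in steps of 0.25. Most of the 955 sequences lie in 1 peak on the positive side, where library 2 holds a median of 25.9 times as many UMIs, and a smaller peak lies on the negative side.

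The first comparison asked which cell classes each library held. Kupffer-like cells, the resident macrophages of the liver sinusoid, were the largest named class of both libraries, with 1803 cells (51.7%, interval 50.0 to 53.4) in library 1 and 2643 cells (38.1%, 36.9 to 39.2) in library 2. Erythroid-like cells, which are of the red cell lineage at any stage, made up 22.0% of library 2 (1526 cells, 21.01 to 22.98) and 0.459% of library 1 (16 cells, 0.262 to 0.744). Of those 16 cells, 13 were shallow shared barcodes. Endothelial-like cells, which line the vessels, were more frequent in library 1, at 11.6% (406 cells, 10.6 to 12.8) against 4.05% (281 cells, 3.596 to 4.538). Conventional dendritic-like cells, which present antigen to T cells, were also more frequent in library 1, at 6.94% (242 cells, 6.12 to 7.83) against 2.56% (178 cells, 2.21 to 2.96). That difference was not found in several other settings, given below.

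Monocyte-like cells made up 2.75% (96 cells, 2.23 to 3.35) of library 1 and 2.54% (176 cells, 2.18 to 2.93) of library 2, with overlapping intervals, but 12.5% and 4.93% with a minimum of 500 genes, 6.51% and 3.37% with at most 40% mitochondrial UMIs, and 3.33% and 1.29% with the shallow shared barcodes left out before clustering. The names monocyte-like and conventional dendritic-like shifted together. With a minimum of 500 genes, library 1 had 339 monocyte-like and 24 conventional dendritic-like cells, against 96 and 242 in the main setting. Library 2 had 287 and 60, against 176 and 178. The higher monocyte-like shares there are therefore not shown to be more monocytes. B-like cells (1.26% and 1.31%) and T or natural killer-like cells (0.831% and 0.879%) had similar shares in both libraries. Stellate or fibroblast-like cells made up 1.26% of library 1 and 3.49% of library 2, but 3.64% and 2.12% with at most 40% mitochondrial UMIs and 1.31% and 1.22% with the shallow shared barcodes left out before clustering. In library 2 this class had Marco at 93.8%, Cd5l at 87.7% and Clec4f at 87.0% of the Kupffer-like level. Hepatocyte-like cells made up 0.172% and 1.44%, but 2.52% and 5.33% with at most 40% mitochondrial UMIs. Neutrophil-like cells made up 0.0860% and 0.418%, but 0.185% and 2.90% with a minimum of 500 genes and 0.224% and 2.42% with the shallow shared barcodes left out before clustering. In library 2 these were 169 and 167 cells with medians of 22467 and 22802 UMIs, against 29 cells with 4018 in the main setting. Mostly other, deeper cells thus took the name. Unnamed clusters held 799 cells (22.9%) of library 1, of which 730 were shallow shared barcodes, and 1615 cells (23.3%) of library 2, of which 6 were. The largest unnamed cluster of library 2 held 1027 shallow cells with a median of 929 UMIs.

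**Figure D2:**
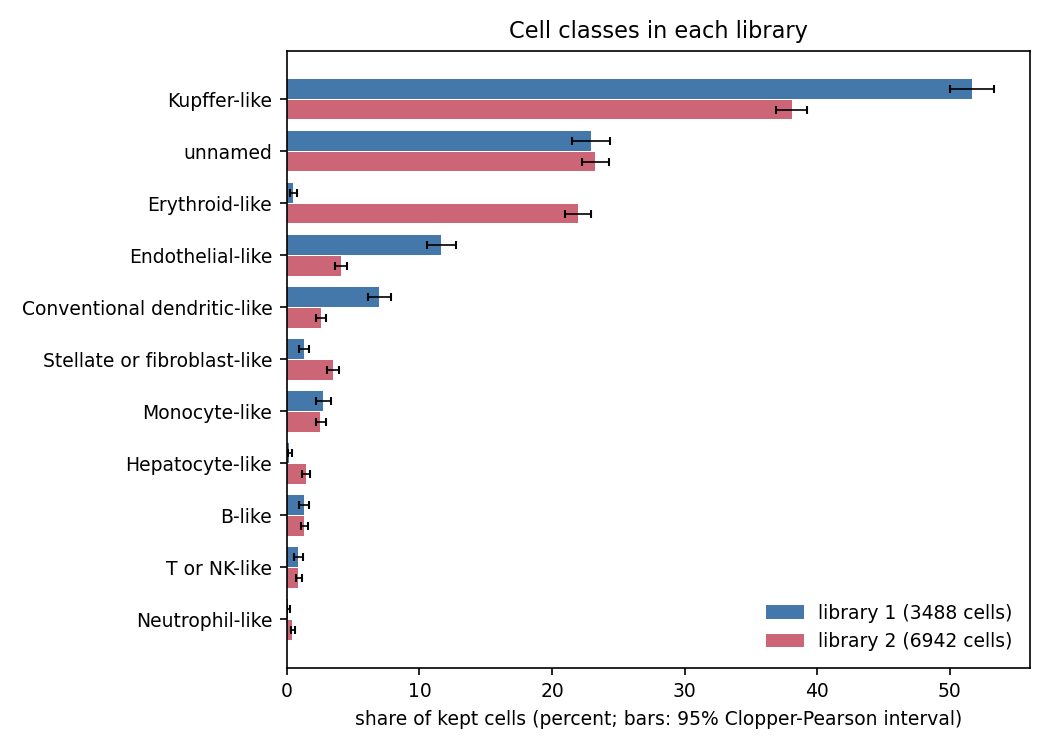
Share of kept cells in each named class and in the unnamed clusters (percent), for library 1 and library 2, with bars for the exact 95% intervals. Erythroid-like cells stand at 22.0% in library 2 and 0.459% in library 1, and Kupffer-like cells at 38.1% and 51.7%.

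Without the shallow shared barcodes, Kupffer-like cells made up 66.4% (64.5 to 68.2) of 2673 cells in library 1 and 38.0% (36.8 to 39.1) of 6898 cells in library 2. Erythroid-like cells then made up 0.112% (3 cells) and 22.1%, endothelial-like cells 14.4% and 4.06%, conventional dendritic-like cells 8.72% and 2.42%, and unnamed clusters 2.58% and 23.3%. The bead enrichment, the mitochondrial filter and the difference in depth act on all of these shares. The higher erythroid-like share in library 2 held under every alternative run. It moved to 0.111% and 12.3% with a minimum of 500 genes, and to 17.3% and 31.9% with at most 10% mitochondrial UMIs. The higher endothelial-like share in library 1 also held, but the 0% of library 2 with at most 10% mitochondrial UMIs reflects naming. The Kupffer-like shares had overlapping intervals with a minimum of 500 genes (61.4%, 59.5 to 63.2, and 63.2%, 62.0 to 64.5). With 3000 variable genes, the Kupffer-like share was higher in library 2 (48.9% and 55.6%). In that setting, 528 of 1707 Kupffer-like cells of library 1 were shallow shared barcodes, and 36.4% of library 1 was unnamed. The conventional dendritic-like shares had overlapping intervals with a minimum of 500 genes (0.888% and 1.03%), at most 10% mitochondrial UMIs (2.07% and 2.10%), 3000 variable genes (0.860% and 0.980%) and resolution 2 (1.63% and 1.41%). The share was higher in library 2 with at most 40% mitochondrial UMIs (0.558%, 0.395 to 0.764, and 0.989%, 0.798 to 1.21). At resolution 0.5 no cluster took the name. The Kupffer-like shares were 66.2% and 55.8% when 2 shallow clusters that scored as Kupffer-like were named as well.

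The second comparison asked how expression in Kupffer-like cells differed between the libraries. Kupffer-like cells of library 2 had far more RNA of the heme oxygenase gene Hmox1, of the ferritin gene Fth1, of the scavenger receptor gene Marco and of 5 of 6 genes of the lipid-associated macrophage state. They had far less RNA of the MHC class II genes, which encode the proteins that present peptides to helper T cells. The class held 9272020 UMIs in library 1 and 25091540 in library 2. Different clusters made up the class in each library. Cluster 0 held 93.7% of it in library 1, while clusters 1 (43.2%), 2 (40.2%) and 10 (13.0%) held most of it in library 2. Leading genes of cluster 0 against all other cells, among them the other Kupffer-like clusters, included Cd207, a marker of capsule macrophages, and no Kupffer marker. Against clusters of other classes, they included the Kupffer marker Clec4f as well as Cd207. Cluster 0 met the naming rule with 11 Kupffer markers and scored 0.99 for Kupffer. Trem2 and Cd9, which stand beside Cd207 in the list for capsule macrophages, went the other way and were higher in Kupffer-like cells of library 2. Values for clusters 0, 1, 2 and 10 alone are given as well and do not test the name.

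Among 15 heme and iron handling genes, 7 were at least 2-fold higher in library 2, 1 at least 2-fold lower and 7 within 2-fold. Their median log2 ratio was 0.97, percentile 100 among matched random lists. Hmox1 (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589, GRCm38), the heme oxygenase that opens the heme ring, had 1031 CPM (1010 to 1052) in library 1 and 8077 CPM (8042 to 8112) in library 2, 7.84-fold higher (log2 ratio 2.97, 2.941 to 2.9999). The ferritin heavy chain gene Fth1 was 6.20-fold higher (2.63, 2.62 to 2.65), and the light chain gene Ftl1 had a log2 ratio of 1.26. Spic (chromosome 10, 88674772 to 88685015), a transcription factor of iron-recycling macrophages, was 3.25-fold higher (1.70, 1.60 to 1.80). Slc48a1, which carries heme out of the phagolysosome, had a log2 ratio of 1.66, and Blvra, a biliverdin reductase that acts on the product of Hmox1, had 0.97. Slc40a1 (chromosome 1, 45908068 to 45926523), the iron exporter ferroportin, had 3439 and 3012 CPM and a log2 ratio of -0.19 (-0.21 to -0.17), which was 0.03 with the size factor. Cd163 (chromosome 6, 124304656 to 124330527), the receptor for haptoglobin-hemoglobin complexes, went the other way, with 691 CPM in library 1 and 121 in library 2 (-2.51, -2.58 to -2.45).

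Globin RNA moved with these genes. All 6 measured globin and erythroid genes were at least 2-fold higher in Kupffer-like cells of library 2, with a median log2 ratio of 7.01 (percentile 100). The globin genes made up 5.92% of UMIs in Kupffer-like cells of library 2 and 0.0439% in library 1. They also made up 4.25% in B-like and T or natural killer-like cells of library 2, which do not make globin. Hbb-bs, a beta-globin gene, had 200 CPM in library 1 and 26464 in library 2. Hba-a1 and Hba-a2, and Hbb-bs and Hbb-bt, are near-identical copies whose split is uncertain.

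NRF2 targets, which protect against oxidants and are also induced by heme, had a median of 0.87 (percentile 100), with 4 of 10 at least 2-fold higher and 6 within 2-fold. Prdx1, a peroxidase, had 1.73, Gclm, a subunit of the enzyme that starts glutathione synthesis, 1.66, and Txnrd1, a thioredoxin reductase, 1.10. Of 6 lipid-associated macrophage genes, 5 were at least 2-fold higher and 1 within 2-fold (median 3.23, percentile 100, with 1 gene at its bound). Fabp5, a fatty acid carrier, had a log2 ratio of 4.28, and the tetraspanin genes Cd63 and Cd9 had 3.45 and 3.01. Trem2, a lipid receptor, had 1.75.

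All 7 MHC class II genes were at least 2-fold lower in library 2 (median -3.94, percentile 0). H2-Aa (ENSMUSG00000036594, chromosome 17, 34282744 to 34287823), an alpha chain gene, had 2778 CPM (2744 to 2812) in library 1 and 103 CPM (99.3 to 107) in library 2, 26.9-fold lower (log2 ratio -4.75, -4.81 to -4.69). H2-Eb1 and H2-Ab1, which encode beta chains, had -4.63 and -4.25. Cd74, the invariant chain that guides class II proteins, was 12.7-fold lower (-3.67).

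Inflammatory genes moved in both directions. Of 10 measured cytokines and NF-kB targets, 3 were at least 2-fold higher, 4 at least 2-fold lower and 3 within 2-fold, with a median of 0.14 (percentile 98.5) that was -0.39 among members with at least 50 CPM. Il1b (chromosome 2, 129364570 to 129371139), which encodes interleukin-1 beta, was 3.31-fold lower in library 2 (-1.73, -1.84 to -1.61). The inflammasome sensor gene Nlrp3 had -1.33 and the NF-kB inhibitor gene Nfkbia -1.14, while the cytokine genes Il18 and Ccl4 had 1.90 and 1.29. Tnf, a central inflammatory cytokine, had 22 and 30 UMIs (-0.99, -1.83 to -0.13), and Il10, an anti-inflammatory cytokine, 57 and 58 UMIs (-1.41, -1.96 to -0.86). Of 9 alternative activation and anti-inflammatory genes, none was at least 2-fold higher, 4 were at least 2-fold lower and 5 within 2-fold (median -0.61, percentile 3.41). They included Arg1, an arginase, at -2.15, and Mrc1, the mannose receptor, at -0.61. Interferon response genes had a median of -0.68 (percentile 2.69), with 1 of 14 at least 2-fold higher, 6 at least 2-fold lower and 7 within 2-fold. Irf7, which amplifies interferon, had -2.18, and Gbp2, a GTPase, 1.04.

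**Figure D3:**
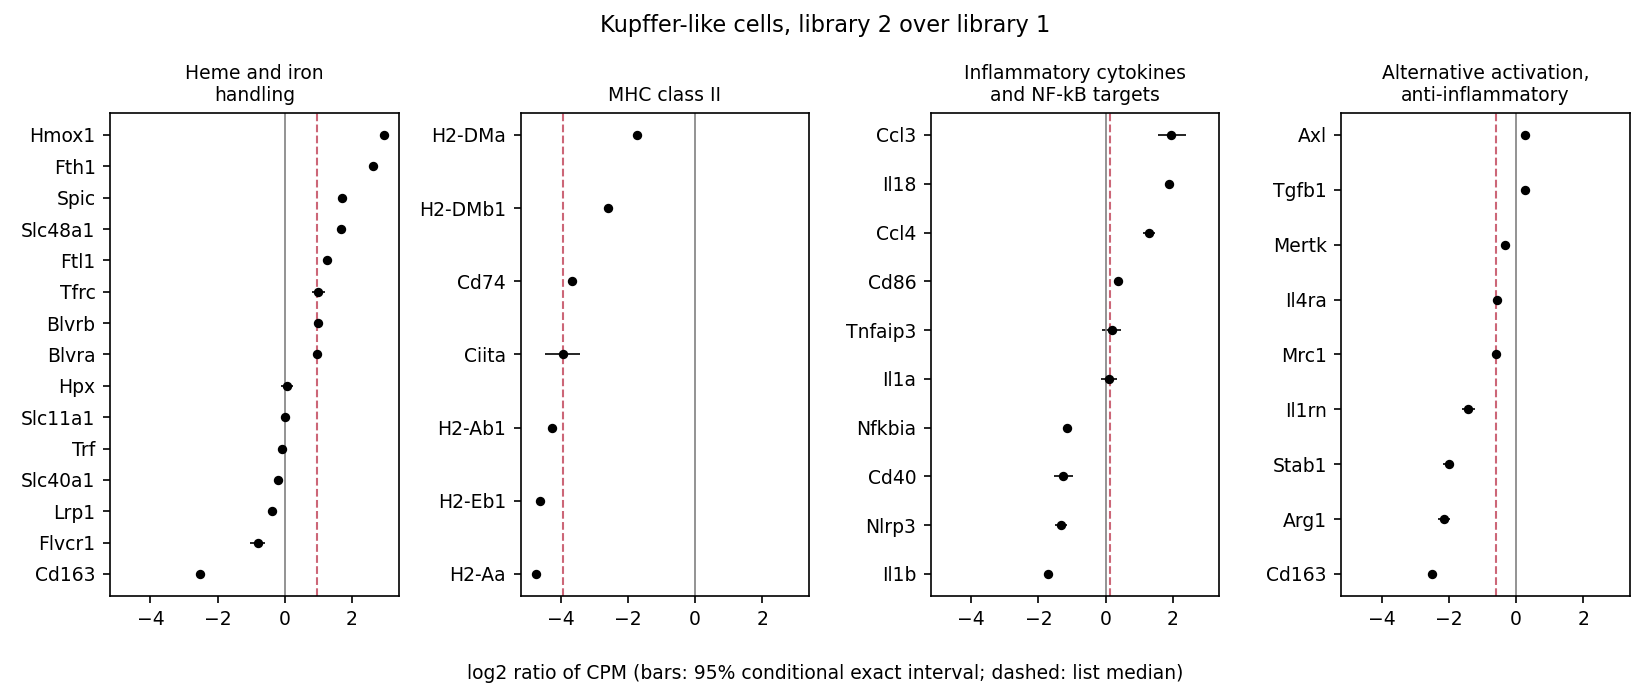
Log2 ratio of CPM (library 2 over library 1) in Kupffer-like cells for the measured members of 4 gene lists, 1 panel per list, with bars for the conditional exact 95% intervals and a dashed line at the list median. Heme and iron genes spread around 0.97 with Hmox1 at 2.97 and Cd163 at -2.51, while all MHC class II genes lie below 0.

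The Kupffer markers Clec4f and Timd4 were within 2-fold, while Marco, also a Kupffer marker, was not. These markers helped to name the class, as did C1qa, C1qb, C1qc, Cd5l and Vsig4 of the scavenger and complement list. Similar levels of them were thus partly set by the choice of clusters. Clec4f (chromosome 6, 83644542 to 83656187), a lectin gene of Kupffer cells, had 4112 and 2611 CPM (-0.66, -0.67 to -0.64), and Timd4, a receptor for dying cells, 361 and 244 CPM (-0.57, -0.63 to -0.50). Of 12 scavenger and complement genes, 11 were within 2-fold (median -0.29, percentile 15.3). The exception was Marco (chromosome 1, 120474538 to 120505024), with 511 CPM (497 to 526) in library 1 and 12608 CPM (12564 to 12652) in library 2, 24.7-fold higher (4.62, 4.58 to 4.67). Lysosome genes had a median of 0.12 (percentile 87.6), with 1 of 12, the protease gene Ctsd at 1.63, at least 2-fold higher and 11 within 2-fold. Cholesterol and lipid genes had a median of -0.29 (percentile 19.99), with 1 of 10 higher, the lipase gene Lpl at 1.04, and 9 within 2-fold. Proliferation genes had a median of -0.64 (percentile 9.89), with 1 of 9 at least 2-fold lower and 8 within 2-fold. That median was 0.09 in the largest clusters alone.

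Extracellular matrix turnover genes had a median of 0.05 (percentile 93.1), with 1 of 5 higher, 1 lower and 3 within 2-fold. Dissociation and stress genes had a median of 0.04 (percentile 96.1), with 3 of 11 higher, 2 lower and 6 within 2-fold. The heat shock genes Hspa1b and Hspa1a had 4.36 and 4.04, and the immediate early gene Fos -1.24. Hepatocyte RNA had a median of -0.47 (percentile 17.6), with 1 of 8 at least 2-fold lower and 7 within 2-fold, and Pf4, the 1 platelet gene measured, had 0.20 (percentile 88.0). Mitochondrial RNA had a median of -0.59 (percentile 0.01), with 3 of 15 at least 2-fold lower and 12 within 2-fold. All 93 measured ribosomal protein genes were within 2-fold (median 0.09, percentile 99.9).

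The 12 highest ratios were those of Hbb-bt (7.24), Hba-a1 (7.13), Hbb-bs (7.05), Slc4a1 (6.96), Hba-a2 (6.87), Sort1 (5.34), Alas2 (4.78), Lgals1 (4.66), Marco, Cd24a (4.36), Hspa1b and Fabp5. Slc4a1, the anion exchanger of red cells, and Alas2, the first enzyme of erythroid heme synthesis, are erythroid genes, while Sort1 encodes a sorting receptor and Lgals1 a galectin. The 12 lowest were those of Cxcl13 (-6.08), H2-Aa, Gbp2b (-4.74), H2-Eb1, H2-Ab1, G6pc (-3.98), Tmem176b (-3.93), Cd207 (-3.71), Cd74, Etnppl (-3.64), Ly6a (-3.55) and Tgfbi (-3.26). Cxcl13, a chemokine that attracts B cells, had 116 CPM in library 1 and 1.71 in library 2.

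In cluster 0 of library 1 against clusters 1, 2 and 10 of library 2, the heme and iron median was 0.94, the MHC class II median -3.88, the lipid-associated macrophage median 3.35, Hmox1 2.96, Marco 4.74, Cd163 -2.54 and H2-Aa -4.77. The median log2 ratio of the 2559 genes with at least 50 CPM in both libraries was -0.22, so ratios relative to the typical gene lie higher by that amount. Relative to it, the heme and iron median was 1.18, the inflammatory median 0.36 and the alternative activation median -0.39. When Kupffer-like cells were chosen by markers in each cell, the heme and iron median was 0.45, the MHC class II median -2.74, the inflammatory median -0.47 and the alternative activation median -1.15. With the 2 shallow clusters named as well, the heme and iron median was 0.88, the MHC class II median -3.99, Hmox1 2.69 and Marco 3.61.

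The third comparison covered the other classes with enough cells. Conventional dendritic-like cells of both libraries had MHC class II RNA at levels within 2-fold of each other, and less RNA of interferon response genes in library 2, where the make-up of the class also differed. All 3 classes had more Hmox1 RNA in library 2, as Kupffer-like cells did, but also more RNA of Marco. Carried-over Kupffer RNA was not separated from RNA of their own. Globin genes were among the highest ratios in all 3 classes.

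In conventional dendritic-like cells (1643212 UMIs in library 1, 1256025 in library 2), all 7 MHC class II genes were within 2-fold (median -0.07, percentile 17.7), with H2-Aa at 6648 and 6347 CPM. Of 14 interferon response genes, 7 were at least 2-fold lower in library 2 and 7 within 2-fold (median -0.88, percentile 0). The chemokine genes Cxcl10 and Cxcl9, which attract T cells, had log2 ratios of -2.78 (-3.20 to -2.38) and -1.53 (-1.69 to -1.37). The matrix protease gene Mmp12 had -2.88, and Il1rn, the interleukin-1 receptor antagonist, -3.14. Hmox1 had 155 CPM in library 1 and 1732 in library 2, and Marco 70.6 and 2502 CPM. In library 2, these levels were 21.4% and 19.8% of those in Kupffer-like cells, beside Cd5l at 19.1% and Clec4f at 16.8%. The lowest ratios were those of Gbp2b (-5.79), Cd207 (-4.17), Cxcl11 (-4.09), Cps1 (-3.33) and Ccl17 (-3.29), and the highest were 4 globin genes and Alas2 (6.67, 4.15 to 11.99). Markers of capsule macrophages scored nearly as high as dendritic markers in this cluster. At resolution 2 only 57 and 98 cells kept the name, and an unnamed cluster of 200 and 76 cells, led by Ccr2, Cxcl9, Cx3cr1 and Cxcl10, scored highest for capsule macrophages. The class therefore mixes cells in different proportions in each library, and a change in its make-up was not separated from a change within its cells.

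In monocyte-like cells (391507 and 992735 UMIs), Hmox1 had 120 CPM in library 1 and 3314 in library 2 (4.79, 4.37 to 5.23), Spic 2 and 196 UMIs (5.27, 3.40 to 8.33) and Marco 16 and 2631 UMIs (6.02, 5.32 to 6.83). In library 2, the Hmox1 level was 41.0% of that in Kupffer-like cells. Genes of high expression in Kupffer cells stood at 44.0% (C1qb), 35.4% (Slc40a1), 34.7% (C1qa), 28.2% (Cd5l), 27.3% (Vcam1), 21.02% (Marco), 17.5% (Cd163) and 16.6% (Clec4f), and Hmox1 in B-like and T or natural killer-like cells together at 40.8%. In library 1, Hmox1 stood at 11.6%, Marco at 7.99%, Slc40a1 at 5.72%, Cd5l at 4.01%, C1qa at 3.76% and Clec4f at 3.17%. Kupffer genes were higher as well, with Cd5l at 261 and 2321 CPM and 9 of 12 scavenger and complement genes at least 2-fold higher (median 2.33, percentile 100). The heme and iron median was 1.61, the MHC class II median -0.67, the proliferation median 2.60 and the inflammatory median 1.66, with Il1b at 30.7 and 95.7 CPM (1.64, 0.77 to 2.64). Hba-a2 and Hbb-bt, with no UMI in library 1, were 292-fold and 290-fold higher when set to the floor of 3 UMIs. The lower 95% limits of their log2 ratios were 7.89 and 7.88. Hbb-bs and Hba-a1, with 2 and 3 UMIs, had log2 ratios of 11.04 (9.18 to 14.08) and 10.09 (8.54 to 12.37). The lowest ratios were those of Lyz1 (-5.36), Flt1 (-3.41), Slc7a2 (-2.97), Ahr (-2.70) and Gramd4 (-2.68).

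Endothelial-like cells (1672312 and 2017676 UMIs) came from different clusters, cluster 8 with 382 of 406 cells in library 1 and cluster 12 with 280 of 281 cells in library 2. Esm1 (chromosome 13, 113209659 to 113218098), a proteoglycan gene of activated endothelium, had 1 and 274 UMIs (7.83, 5.34 to 13.14), and the other 4 highest ratios were those of globin genes. The lowest were those of Cxcl13 (-7.04), Gbp2b (-5.15), G6pc (-4.32), H2-Aa (-4.07) and H2-Eb1 (-3.99). In library 1, H2-Aa reached 43.8% of its level in Kupffer-like cells and Gbp2b 37.8%, close to the Kupffer genes Cd5l (40.2%) and Clec4f (38.7%). Hmox1 had 517 and 5271 CPM (3.35, 3.25 to 3.45), in library 2 65.3% of the Kupffer-like level, beside Slc40a1 at 64.3%, Marco at 61.2%, Cd5l at 59.0% and Clec4f at 50.8%.

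Kupffer RNA was present in cells that do not make it. In library 2, Clec4f reached 35.7% of its Kupffer-like level in B-like cells and 50.4% in T or natural killer-like cells, and Hmox1 36.9% and 47.2%. In library 1, Clec4f reached 17.7% and 12.4%, and Hmox1 12.8% and 6.53%. A UMI of Hmox1 was found in 81.4% and 99.5% of Kupffer-like cells (median depths 4429 and 8720 UMIs) and in 22.7% and 98.9% of B-like cells (2073 and 2609 UMIs). A UMI of H2-Aa was found in 90.3% and 35.0% of Kupffer-like cells and in 34.5% and 8.20% of T or natural killer-like cells (3767 and 2785 UMIs). With each cell thinned to 1000 UMIs, which left out 240 and 31 Kupffer-like cells, the Kupffer-like shares were 51.0% and 97.6% for Hmox1 and 85.2% and 8.27% for H2-Aa.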

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

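Leaving out the shallow shared barcodes was chosen after the data had been seen, while each test given here was set before its own result was seen.

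A signal lay outside the comparisons of the report, since 955 barcode sequences occurred in both libraries. In 937 of these pairs the shallower barcode had less than its partner's UMIs divided by 5, and 886 of those shallow barcodes were in library 1, with a median of 675 UMIs against 17691 for the partner. Among all barcodes of the other library, the partner had the closest expression profile for 88.4% of the shallow barcodes (828 of 937, 86.1 to 90.4), against 0 of 18 in pairs that differed by less than 5-fold. That share argues against different cells that drew the same barcode by chance and is consistent with reads of one library having been assigned to the other. The step at which this happened was not tested, and no biological explanation was tested.

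The heme and iron genes were higher in Kupffer-like cells of library 2, with a median log2 ratio of 0.97. With each cell thinned to 1000 UMIs, the median was again 0.97. Thinning gives each cell equal weight but leaves the expected share of each gene in a cell as it was. The value shows that the greater weight of deeper cells does not account for the ratio. It cannot decide on depth acting through the choice and naming of cells. The median was 0.93 with the shallow shared barcodes left out before clustering, where the newly named class held 1706 and 3844 cells. That value decides nothing on reads of the other library, since other cells entered or left the class as well. In the main class only 29 of 1803 and 24 of 2643 Kupffer-like cells were such barcodes. Free RNA alone was set to need at least 50% of the Kupffer-like Hmox1 level in cells that do not make it, and B-like and T or natural killer-like cells of library 2 had 40.8% (32.1 to 48.7, bootstrap over cells) of it. In B-like cells alone, Hmox1 stood at 36.9% of its Kupffer-like level, beside Slc40a1 at 42.7%, Marco at 38.3% and Clec4f at 35.7%. Slc40a1, with similar CPM in Kupffer-like cells of both libraries, thus lay under 50% there as well. The test therefore cannot decide on the ratio between libraries. A difference in the state of Kupffer-like cells stays a hypothesis, found and tested in the same cells. The free RNA test covered Hmox1 alone and not the other genes of the list. Genotype, the bead pull-down and the single mouse per library stay open and were not tested.

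Globin RNA made up 5.92% of UMIs in Kupffer-like cells of library 2. B-like and T or natural killer-like cells of that library had 34.6% (15.5 to 61.6) as many globin UMIs per cell as Kupffer-like cells, so free RNA as the whole source cannot be told apart from a further source, because few cells carry most of the globin. Unlike the Hmox1 values, this figure is not scaled to depth. It was 45.15% among cells between the depth quartiles of the B-like and T or natural killer-like cells. As a share of UMIs, globin made up 4.25% in those classes. By CPM in library 2, Hba-a1 and Hbb-bs stood at 97.3% and 92.2% of the Kupffer-like level in endothelial-like cells. They stood at 39.1% and 46.4% in conventional dendritic-like cells, and at 38.8% and 40.6% in monocyte-like cells. Globin at the Kupffer-like level was thus not particular to Kupffer-like cells. Relative to globin, Bpgm stood in Kupffer-like cells at 1.27, Alas2 at 0.998 and Slc4a1 at 0.260 of the value in erythroid-like cells, and B-like and T or natural killer-like cells had similar ratios (1.29, 0.974 and 0.367). Erythroid cells in the same droplets and engulfed red cells would both bring globin RNA. The erythroid-like value pools clusters at different levels of maturation genes, so these ratios do not separate the 2 sources. Neither source nor genotype was tested.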

How the results depend on the processing

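Allowing 40% mitochondrial UMIs, leaving out shallow shared barcodes, leaving out the highest doublet scores, comparing the largest clusters alone and naming shallow clusters from the first set of leading genes alone were chosen after the data had been seen. No paired analysis was possible because there was 1 library per group and the comparison comes from no test. Keeping doublets gave no other values, since none had been left out. Of the shares recomputed for each class and library, 98 stayed within the interval of the main value and 100 moved. Of the list medians, 99 stayed there, 87 moved and 8 whose main interval excludes 0 changed sign, and of the named genes in Kupffer-like cells, 141 stayed, 181 moved and 2 changed sign. The erythroid-like share was higher in library 2 and the endothelial-like share higher in library 1 under every setting run, though the endothelial-like share of 0% given below reflects naming. The MHC class II median was negative and the heme and iron median positive under every setting run. Low counts limit Tnf.

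With a minimum of 500 genes, the shares in library 1 and library 2 were 61.4% and 63.2% for Kupffer-like, 0.111% and 12.3% for erythroid-like, 0.888% and 1.03% for conventional dendritic-like and 12.5% and 4.93% for monocyte-like cells, and 4.82% for endothelial-like cells of library 2. With at most 10% mitochondrial UMIs, they were 17.3% (190 of 192 cells shallow shared barcodes) and 31.9% for erythroid-like, 4.06% and 0% for endothelial-like and 2.07% and 2.10% for conventional dendritic-like cells. Library 2 then had 44.2% Kupffer-like and 1.64% monocyte-like cells. With at most 40%, they were 67.7% and 51.3% for Kupffer-like, 0.235% and 20.998% for erythroid-like, 13.2% and 5.14% for endothelial-like, 0.558% and 0.989% for conventional dendritic-like and 6.51% and 3.37% for monocyte-like cells. At resolution 0.5, they were 67.9% and 57.1% for Kupffer-like cells, 0% and 0% for conventional dendritic-like and monocyte-like cells, and 9.98% for endothelial-like cells of library 1. At resolution 2, they were 68.6% and 45.6% for Kupffer-like and 1.63% and 1.41% for conventional dendritic-like cells, and 8.14% for endothelial-like cells of library 1. With 3000 variable genes, they were 48.9% and 55.6% for Kupffer-like, 0.860% and 0.980% for conventional dendritic-like and 0% and 0% for monocyte-like cells, and 9.69% for endothelial-like cells of library 1. With shallow shared barcodes left out before clustering, they were 63.8% and 55.7% for Kupffer-like, 0.112% and 20.1% for erythroid-like and 10.03% and 4.12% for conventional dendritic-like cells. Endothelial-like cells then made up 13.3% of library 1 and monocyte-like cells 3.33% of library 1 and 1.29% of library 2. With the highest doublet scores left out, they were 64.7% and 40.1% for Kupffer-like, 3.23% and 1.39% for conventional dendritic-like and 0% and 0% for monocyte-like cells, and 8.26% for endothelial-like cells of library 1. With the first set of leading genes alone, they were 66.2% and 55.8% for Kupffer-like cells. A share of 0% in both libraries means that no cluster took the name. The 0% for endothelial-like cells of library 2 reflects naming, since an unnamed cluster there (25 and 77 cells) was led by endothelial genes such as Clec4g and Ptprb.

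In Kupffer-like cells, the heme and iron median was 0.69 with at most 10% mitochondrial UMIs, 1.03 with at most 40%, 1.05 without globin, hepatocyte, mitochondrial and ribosomal genes, 1.18 with the size factor and 0.45 with cells chosen by markers. The MHC class II median was -3.57 with at most 40% mitochondrial UMIs, -3.45 with thinned cells and -2.74 with cells chosen by markers. The inflammatory median was 0.36 with the size factor, -0.39 over members with at least 50 CPM and -0.47 with cells chosen by markers. The alternative activation median was -0.57 with the first set of leading genes alone, -0.50 with at most 40% mitochondrial UMIs, -0.52 without globin, hepatocyte, mitochondrial and ribosomal genes, -0.39 with the size factor and -1.15 with cells chosen by markers. That choice took 1912 and 4575 cells, of which 1047 and 1174 were in the Kupffer-like class, so other cells entered by construction.

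Values that changed sign were Slc40a1, at 0.026 with the size factor, and Tnf, at 0.25 with at most 10% mitochondrial UMIs. Ribosomal proteins had -0.031 with at most 10%. With cells chosen by markers, lysosome genes had -0.50, proliferation genes 1.78, hepatocyte RNA 0.25 and platelet RNA -0.53. Proliferation genes had 0.078 with shallow shared barcodes left out, 0.14 with the highest doublet scores left out and 0.085 in the largest clusters alone. The last of these leaves out cluster 15, a proliferating cluster with 5.55% of the class in library 1 and 2.76% in library 2. The inflammatory, dissociation and stress, and matrix turnover medians, whose main intervals hold 0, also turned negative in some settings. For the other changes, of sign or of size, the cause was not tested.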

Other observations

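The erythroid-like cells of library 2 fell into 3 clusters at different levels of red cell maturation genes, and none of the values in this part comes from a test. Cluster 9 (346 cells, median 16504.5 UMIs) had, of the 3, the most RNA of Klf1, a transcription factor of erythroid precursors (367 CPM, 353 to 382), and of Car1, an early carbonic anhydrase gene (707 CPM), with Hbb-bs at 47671 CPM. The proliferation gene Mki67 stood there at 928 CPM. Cluster 11 (322 cells, median 6591 UMIs) had, of the 3, the most RNA of the membrane gene Slc4a1 (2704 CPM, 2637 to 2772), with Mki67 at 1241 CPM and Hbb-bs at 248192 CPM. Cluster 4 (858 cells, median 1577.5 UMIs) had Hbb-bs at 283044 CPM and Alas2 at 1605 CPM, while Klf1 stood at 2.91 CPM and Mki67 at 40.7 CPM.

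Smaller unnamed clusters held other programs. Cluster 21 (11 cells of library 1, 19 of library 2) was led by Saa3, an acute phase gene, Prg4, a lubricating proteoglycan gene, and Retnla, a gene of alternatively activated macrophages, at 1786, 2290 and 1798 CPM in library 1 and 4699, 2924 and 1958 CPM in library 2. Cluster 6 was led by the platelet gene Pf4 and by the granule genes Elane and Mpo of myeloid progenitors. It held 226 cells of library 1, of which 225 were shallow shared barcodes, and 272 cells of library 2, where Pf4 stood at 8665 CPM. Cluster 5 held 475 cells of library 1, of which 474 were shallow shared barcodes, and 207 cells of library 2.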
